A study of Homo sapiens with 4 samples.

How the data were processed

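The data are array intensities of 4 samples of HCT-116 dicer- cells: 2 mock transfections, 1 transfection with the intact miR-124 duplex and 1 with the segmented miR-124 duplex, the duplexes at 10 nM and all at 24 h. Total RNA was amplified and labelled with biotin, per the labels' protocols. The deposited table gives 1 intensity per probe set and array on a linear scale, made with RMA (background correction, quantile normalization and summarisation of probes) per the submitters' processing notes; the version is not given in the sources used here. RMA gives log2 values, so the deposited intensities, from 2.51 to 22268, were taken as values brought back to the linear scale. Quantile normalization gives all arrays nearly the same distribution, so a change of the same size in most genes would be removed. Probe-level data were not used here.

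Intensities were turned into log2 values with no pseudocount. Probe sets were named through an annotation of the array platform, and symbols were updated through Entrez identifiers to a RefSeq gene table of GRCh38.p14, which 35134 probe sets matched and 50 did not. Of 52377 probe sets, 35184 had 1 gene, 374 several and 16819 were not listed. Probe sets with several genes or none entered no gene-level result and name no gene. For the 8731 genes with several probe sets, the one with the highest mean over the 4 arrays stood for the gene; where probe sets of a named gene past the test disagreed in direction, this is said in the text. No coordinates are given, since the files name no genome build.

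Changes were tested with limma 3.58.1 in R 4.3.3, with a mean for each of the 3 groups over all 4 arrays, moderated by eBayes, at a Benjamini-Hochberg adjusted p of 0.05 over 19798 genes per comparison. There was 1 residual degree of freedom, from the mock pair, and the prior had 2.89 degrees of freedom. A lone treated array is assumed to vary like the mock arrays, and the comparison of the 2 duplexes takes its spread from the mock pair alone. Genes at least 1.5-fold from both mock arrays the same way were counted beside the same count for one mock array against the other. The correlation and covariance of both sets of changes were set beside simulated unchanged arrays and beside values with a different mock array for each duplex.

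There were 13 gene lists, written before the data were examined: miR-124 targets from the literature, small RNA pathway, interferon response, neuronal, cell cycle and proliferation, p53 targets, unfolded protein and amino acid stress response, sterol synthesis, adhesion with matrix and actin, epithelial and colon, markers of other cell types, housekeeping, and immediate early and apoptosis. The literature list was written from general knowledge, and nothing records whether any of its members was chosen by others on these arrays. The median change of a list was placed among 10000 random lists of the same size drawn from 20 bins of mean level. The percentile describes these arrays and is no p-value. Members past the limma threshold were counted over all genes and adjusted over the list alone.

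The genes named were fixed by rule before the data were examined: for each duplex against mock the 12 largest falls and 8 largest rises past the threshold, going the same way against both mock arrays, with a level in the higher group above the median of all genes (log2 6.76). For the difference of the duplexes the 5 largest each way were named, although none passed. DICER1 and 11 literature targets were to be named if measured, and up to 4 members of each list with the largest change served as examples. EFNB1, CDKN1A, MDM2, EPCAM and, for the intact duplex, LSS were named after their values were seen.

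The limma test was tried on simulated data of 19798 genes. For the intact duplex against mock with 200 changed genes, 2% of changes of 1 log2 unit and 84% of changes of 2 units were recovered, and 9.47% of calls were false. With 4000 changed genes, 87.7% and 98.5% were recovered, and 4.14% of calls were false. For the difference of the duplexes with 200 changed genes 0% were recovered at either size, and with 4000 changed genes 78.7% and 97.2%. The variances were drawn from the prior that limma had fitted, and simulated treated arrays varied like the mock arrays. These rates therefore do not cover a treated array that varies more than the mock arrays. The list placing was tried on the measured difference of the mock arrays. Of 50 lists of 30 genes drawn at random and shifted by 0.2, 98% lay under the 2.5th percentile of random lists, against 2% of unshifted lists. The SD over genes was 0.241 for the mock difference, 0.673 for the intact and 0.463 for the segmented duplex against mock. The 98% therefore does not carry over to the comparisons with a duplex, where random lists spread wider.

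The alternatives were a further quantile normalization, centring each array on its median, leaving out the dimmest 40% of genes, eBayes with trend and robust prior, the mean of all probe sets of a gene, a fold threshold, only the groups compared, and leaving out each mock array for values that need no test. Planned tests of seed sites and of 7-base words in 3′ untranslated regions were not run, because no transcript or genome sequence was used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.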

Results

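Gene expression was measured on 4 one-colour arrays of total RNA from HCT-116 cells labelled dicer-, a human colon carcinoma line altered in Dicer, the enzyme that cuts microRNA precursors. The cells were collected 24 h after transfection. There were 2 mock-transfected arrays, 1 array of cells given 10 nM of a miR-124 duplex with an intact guide strand, and 1 array of cells given 10 nM of a miR-124 duplex whose guide strand was segmented, in a way that the labels give only as a code. miR-124 is a microRNA abundant in neurons, and a microRNA lowers messenger RNAs that pair with its 5′ part, the seed. The series asks whether such activity is kept when the guide strand is segmented. Each array had 52377 probe sets, and 19798 genes had at least 1 probe set assigned to that gene alone. The median intensity over probe sets was 44.3 and 42.6 on the mock arrays, 46.3 with the intact duplex and 45.3 with the segmented duplex. Across genes, log2 levels correlated with r = 0.997 between the mock arrays, and with r = 0.993 between the duplexes. Between mock and the intact duplex r was 0.977 and 0.976, and between mock and the segmented duplex 0.989 and 0.988; genes are not independent replicates. The number of arrays limits the precision of every value. Each duplex has no replicate check, so limma's test assumes that a lone treated array varies like the 2 mock arrays. Nothing in the labels says that the mock arrays came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

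DICER1, the gene of Dicer, had a log2 level of 11.24 ± 0.05 (SD, n = 2) on the mock arrays, 11.13 with the intact duplex and 10.80 with the segmented duplex. The differences from mock, -0.11 and -0.45, had limma adjusted p-values of 0.56 and 0.122. All 5 of its probe sets went the same way as the 1 used. No array of unaltered cells was analysed here, and a probe set outside the altered part of the gene says nothing about the alteration.

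With the intact miR-124 duplex, 4937 of 19798 genes differed from mock, 2064 lower and 2873 higher. CENPQ, a kinetochore protein gene, fell by 4.31 on the log2 scale, from 10.88 ± 0.05 (SD, n = 2) to 6.57, a 19.8-fold difference (limma SE 0.12, adjusted p = 0.00822). PAPSS2, which makes the sulfate donor of the cell, fell by 3.59, from 9.07 ± 0.02 to 5.48. The replication genes DTL and MCM10 fell by 3.69 and 3.58. The other large falls were those of ATP6V0E1, a subunit of the vacuolar proton pump (-3.55), KDELR3, a retrieval receptor for endoplasmic reticulum proteins (-3.54), ADI1 of the methionine salvage pathway (-3.50), STOM (-3.50), the transcription factor MYB (-3.50), SUCLG2 of the citric acid cycle (-3.47), the cationic amino acid transporter SLC7A2 (-3.42) and the ceramide synthase CERS2 (-3.41).

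The 8 genes named for the largest rises with the intact duplex all lay below the median level of genes (log2 6.76) in mock cells. ABCA1, the cholesterol exporter, rose from 4.86 ± 0.07 (SD, n = 2) to 9.32 (log2 change 4.46, limma SE 0.13, adjusted p = 0.00822). PLA2G4D, a phospholipase, rose by 4.52 from 3.41 ± 0.02. CXXC4 rose by 4.58 from mock levels of 4.39 and 3.36, with a limma adjusted p of 0.0116. The histone gene H2BC11 (4.03), the lipid transporter gene ABCA12 (3.94), TMT1A (3.93), PROM2 (3.82) and the sodium channel gene SCN2A (3.74) rose as well. No detection call was used here, so whether the mock values of these genes lie above background was not tested, and the sizes and order of the rises depend on it.

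Of the 55 measured genes on a list of miR-124 targets taken from the literature, 36 fell and 1 rose with the intact duplex, and 18 did not pass; adjusted over the list alone, 39 fell and 1 rose. SUCLG2 fell by 3.47, the vesicle fusion gene VAMP3 by 3.08 and the small GTPase gene RHOG by 2.70. PTBP1, a splicing regulator, fell by 2.53, from 12.26 ± 0.02 (SD, n = 2) to 9.73. The integrin gene ITGB1 (-2.49), the sialomucin gene CD164 (-2.48), the scaffold gene IQGAP1 (-2.39), the collagen-modifying enzyme gene PLOD3 (-2.25) and the laminin gene LAMC1 (-2.17) fell as well. The kinase gene CDK6 fell by 1.58 and the phosphatase gene CTDSP1 by 1.39. One probe set of LAMC1 and one of CDK6, of 4 each, went the other way. EFNB1 was the member that rose, by 0.91. AHR, at -0.23, did not pass by either adjustment, and SLC16A1 had no probe set of its own. The median log2 change of the list was -1.03, and 0 of 10000 random lists of genes of like level had a lower median. Between the mock arrays themselves the list's median was 0.03, at percentile 99.4 of such lists.

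Cell cycle genes were lower and p53 target genes higher with the intact duplex. Of 47 measured cell cycle and proliferation genes, 25 fell, 0 rose and 22 did not pass; adjusted over the list alone, 33 fell and 0 rose. The S phase kinase gene CDK2 fell by 3.33, from 11.20 ± 0.05 (SD, n = 2) to 7.86, its partner cyclin gene CCNE2 by 3.22, CDK4 by 2.92 and the replication helicase gene GINS2 by 2.84. The median of the list was -0.62, below all 10000 random lists. Of 27 measured p53 targets, 18 rose, 0 fell and 9 did not pass; adjusted over the list alone, 20 rose and 0 fell. TP53I3 rose by 2.65, from 9.69 ± 0.04 to 12.35, SESN1 by 2.24, the death receptor gene FAS by 1.89 and GDF15 by 1.86. The median was 0.88, above all 10000 random lists. The p53 target CDKN1A (-0.12) did not pass by either adjustment, and MDM2 (0.40) passed only adjusted over the list alone (limma adjusted p = 0.0429, against 0.0928 over all genes).

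Genes of sterol synthesis were lower as a group. Of 21 measured members, 11 fell and 1 rose, and 12 fell and 1 rose adjusted over the list alone. DHCR7, the last enzyme of cholesterol synthesis, fell by 2.18, the sterol carrier gene STARD4 (-1.79), ACAT2 (-1.45) and LSS (-1.25) fell too, while TM7SF2 rose by 1.44. The median was -0.60, and 0 random lists lay lower. Among 25 immediate early and apoptosis genes 9 fell and 1 rose (12 and 2 adjusted over the list alone). BCL2, which holds back apoptosis, fell by 2.36, EGR1 by 1.55 and MYC by 1.35, and the pro-apoptotic BCL2L11 rose by 1.62. The median of -0.29 lay at percentile 0.28.

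Other lists had medians inside the range of random lists while single members changed. Of 40 adhesion, matrix and actin genes, 12 fell and 5 rose (13 and 6 adjusted over the list alone); 7 of the 12 that fell are also on the literature target list. Of 36 neuronal genes, 9 rose and 1 fell, both over all genes and adjusted over the list alone. RTN1 rose by 2.89, SCG2 by 2.30, PTBP2, the neuronal relative of PTBP1, by 2.01 and MAP2 by 1.89. The neuronal median of 0.04 lay at percentile 66.2, and was 0.62 with the dimmest 40% of genes left out and -0.05 with arrays centred on their medians. The value of 0.62 covers only the brighter members. Of 43 interferon response genes, 10 rose and 1 fell, with the same counts adjusted over the list alone, and the median of 0.17 lay at percentile 92.2; without mock array 2 it was 0.03. IFIT1 rose by 1.77 and IFIT2 by 1.49, and DTX3L fell by 1.52. Of 24 small RNA pathway genes, 4 rose and 4 fell by either adjustment, among them AGO4, an Argonaute gene, which rose by 1.63, and GEMIN4, which fell by 1.42.

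For the unfolded protein and amino acid stress list (28 genes), 3 fell and 2 rose by either adjustment, and TRIB3 fell by 1.80. On the epithelial and colon list (29 genes) 3 fell and 5 rose (4 and 6 adjusted over the list alone); TSPAN8 rose by 1.99, the splicing regulator gene ESRP1 fell by 1.52 and EPCAM stood at 0.02. Of 26 markers of other cell types, 1 fell and 2 rose (0 and 2 adjusted over the list alone); ACTA2, a smooth muscle actin gene, rose by 2.23 and COL1A1 by 1.20. Of 16 housekeeping genes, 2 fell and 1 rose (1 and 0 adjusted over the list alone), with ACTB, which fell by 1.01, the one that stood furthest from mock. The medians of these lists, -0.04, 0.10, -0.04 and -0.04 in that order, lay at percentiles 19.0, 83.8, 47.8 and 24.8. With the dimmest 40% of genes left out the markers of other cell types had a median of 0.68. That value covers only the brighter markers, ACTA2 and COL1A1 among them, and is not a shift of the whole list.

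The limma count rests on 1 residual degree of freedom and was 7809 genes (3143 lower, 4666 higher) in place of 4937 when the prior variance followed the level and was fitted robustly. By size alone, 4589 genes stood at least 1.5-fold from both mock arrays with the intact duplex, against 639 genes that far apart between the mock arrays; the rule asks for both differences with a duplex and for a single one between the mock arrays.

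With the segmented duplex, 1186 genes differed from mock, 531 lower and 655 higher. PAPSS2 fell by 3.30, from 9.07 ± 0.02 (SD, n = 2) to 5.77, a 9.83-fold difference (limma SE 0.12, adjusted p = 0.0349). The collagen gene COL12A1 fell by 3.24, from 10.64 ± 0.01 to 7.40. CENPQ (-3.17), ADI1 (-2.98), ATP6V0E1 (-2.83), VAMP3 (-2.73) and SUCLG2 (-2.62) followed. The ubiquitin ligase gene NEDD4 was 5.65-fold lower, and CDK4 (-2.47), LITAF (-2.46), the phosphatase gene CTDSPL (-2.41) and the retroviral envelope gene ERVMER34-1 (-2.41) fell too. TMT1A rose by 4.10, from 3.85 ± 0.17 to 7.95, also with no detection call for the mock level. ABCA1 rose by 2.98, the Wnt ligand gene WNT2B by 2.84, the histone gene H2AC11 by 2.71, SCN2A by 2.60, PROM2 by 2.49 and NHSL1-AS1 by 2.41, and the histone gene H2BC5 was 5.67-fold higher.

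Of the 55 literature targets of miR-124, 21 fell, 0 rose and 34 did not pass with the segmented duplex; adjusted over the list alone, 34 fell and 0 rose. VAMP3, SUCLG2, CTDSPL and CD164 (-2.16) had the largest changes. IQGAP1 fell by 2.03, LAMC1 by 1.68, CDK6 by 1.23, PTBP1 by 1.17, ITGB1 by 0.93 and CTDSP1 by 0.92; 1 of 4 probe sets of LAMC1 went the other way. PLOD3, at -0.67, passed only adjusted over the list alone (limma adjusted p = 0.0488, against 0.138 over all genes), and AHR, at 0.37, did not pass by either adjustment. With the mean of all probe sets of a gene in place of the brightest, LAMC1 (-0.59) and CTDSP1 (-0.58) missed the threshold, with limma adjusted p-values of 0.139 and 0.0896. The median of the list was -0.57, below all 10000 random lists.

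The medians of the cell cycle, p53, sterol and immediate early lists had the same signs with the segmented as with the intact duplex, with fewer members past the test. Of 47 cell cycle genes 9 fell, 0 rose and 38 did not pass (13 fell and 0 rose adjusted over the list alone): CDK4 fell by 2.47, CDK2 by 1.49, GINS2 by 1.47 and CDK6 by 1.23. The median was -0.20, below all random lists, but that of its 19 mitosis members, a part split off after the data were examined, was -0.01. Of 27 p53 targets 6 rose and 0 fell (16 and 2 adjusted over the list alone): SESN1 rose by 1.45, TP53I3 by 1.43, GDF15 by 1.17 and BBC3 by 1.04. The median of 0.46 lay above all random lists, and MDM2 (0.01) did not pass by either adjustment. CDKN1A (-0.56) was one of the 2 that fell adjusted over the list alone (limma adjusted p = 0.0213, against 0.0823 over all genes). Of 21 sterol synthesis genes 3 fell and 1 rose (8 and 1 adjusted over the list alone), with STARD4 at -1.20, DHCR7 at -1.18, LSS at -1.13 and TM7SF2 at 1.07; the median of -0.34 lay at percentile 0.01. Of 25 immediate early and apoptosis genes 4 fell and 0 rose (7 and 1 adjusted over the list alone), BCL2 by 1.52, JUN by 1.13, MYC by 1.08 and EGR1 by 1.07; the median of -0.24 lay at percentile 0.01.

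Among interferon response genes 4 rose and 0 fell with the segmented duplex (8 and 1 adjusted over the list alone): IFIT1 by 1.42, IFIT2 by 1.24, IFI44 by 1.10 and HERC6 by 1.04. The median of 0.16 lay at percentile 97.4. Of 36 neuronal genes 4 rose and 0 fell (10 and 1 adjusted over the list alone): SCG2 by 1.90, PTBP2 by 1.74, KIF5C by 1.36 and RTN1 by 1.31, with a median of 0.08 at percentile 88.3 and of 0.52 with the dimmest 40% of genes left out. The neuronal median of 0.52 covers only the brighter members. For RTN1, 1 of 3 probe sets went the other way with the segmented duplex. Of 24 small RNA pathway genes 1 rose, AGO4, by 1.54, and 0 fell (1 and 1 adjusted over the list alone); the median of -0.02 lay at percentile 18.1. Of 40 adhesion, matrix and actin genes 7 fell and 2 rose (11 and 3 adjusted over the list alone), with a median of -0.02 at percentile 9.48. On the epithelial and colon list 1 fell and 2 rose (1 and 3 adjusted over the list alone), with ESRP1 at -1.55 and TSPAN8 at 1.49 among them, and the median of 0.06 lay at percentile 77.5. On the unfolded protein and amino acid stress list 1 fell, TRIB3 (-0.94), and 0 rose (1 and 1 adjusted over the list alone), and the median of -0.10 lay at percentile 1.58. Of the markers of other cell types and of the housekeeping genes 0 passed by either adjustment, with medians of 0.03 and 0.01 at percentiles 84.5 and 39.4.

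The segmented count depended on the settings of the fit. It was 4781 genes when the dimmest 40% were left out first, and 5415 with the trended and robust prior. By size alone, 2428 genes stood at least 1.5-fold from both mock arrays, 968 lower and 1460 higher.

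**Figure D1:**
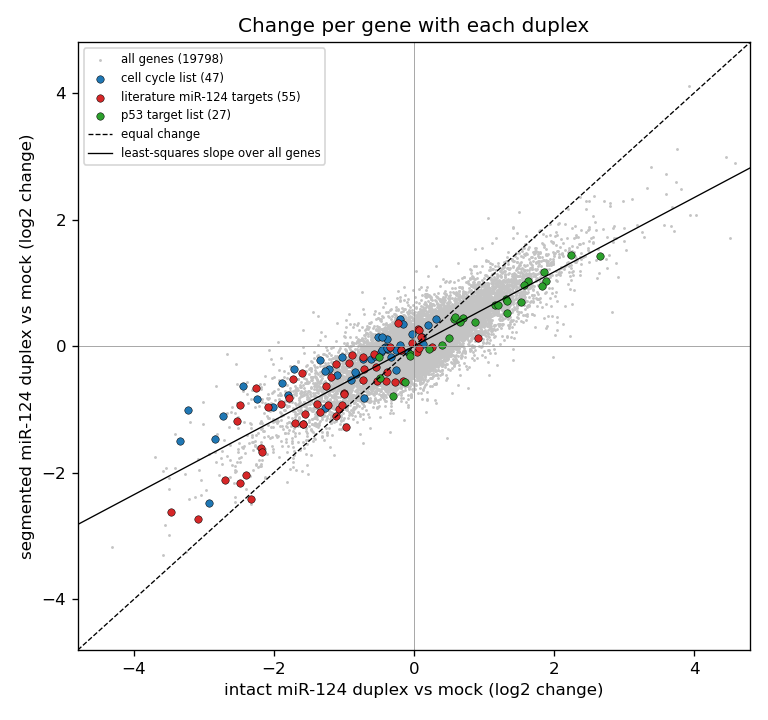
Each point is 1 of 19798 genes, with its log2 change against the mean of the 2 mock arrays with the intact duplex on the horizontal axis and with the segmented duplex on the vertical axis. Coloured points are the cell cycle list (47 genes), the literature targets (55) and the p53 targets (27); the dashed line marks equal changes and the solid line has the least-squares slope of 0.587.

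The changes with the 2 duplexes ran in parallel across genes. Pearson's r was 0.852, Spearman's rho 0.776 and the covariance 0.265, and 78.1% of genes had the same sign. Both comparisons use the same mock arrays, and simulated unchanged arrays set against such mocks gave a mean r of 0.333, a covariance of 0.00854 and the same sign in 60.8% of genes. The observed covariance exceeded the simulated one by 0.257. With a different mock array for each duplex, r was 0.770 and 0.766 and the covariance 0.252 and 0.249. Genes are not independent replicates. Of 531 genes lower with the segmented duplex 510 were also lower with the intact duplex, against 55.4 for independent lists, and of 655 higher 645 were shared, against 95.1. In simulated unchanged arrays the comparisons shared 3.2 calls on average and at most 17. These simulations made only 25.25 calls on average for the intact comparison, far fewer than the measured arrays. Their shared calls therefore cannot size the overlap that shared mock arrays would give here. Part of the excess of shared calls over independent lists may come from the shared mock arrays. Genes called with one duplex are chosen for a large change with that duplex. Of the genes called with the segmented duplex, the change was nevertheless larger with the intact duplex for 413 of the 531 that fell, with medians of -1.56 (intact) and -1.15 (segmented), and for 554 of the 655 that rose, with medians of 1.48 and 1.11. Among genes called with the intact duplex, which this choice favours, it was larger with the intact duplex for 1917 of 2064 and 2715 of 2873. Over all genes, split by the sign of the sum of both changes, it was larger with the intact duplex for 6347 of 9719 lower and 7092 of 10079 higher genes.

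**Figure D2:**
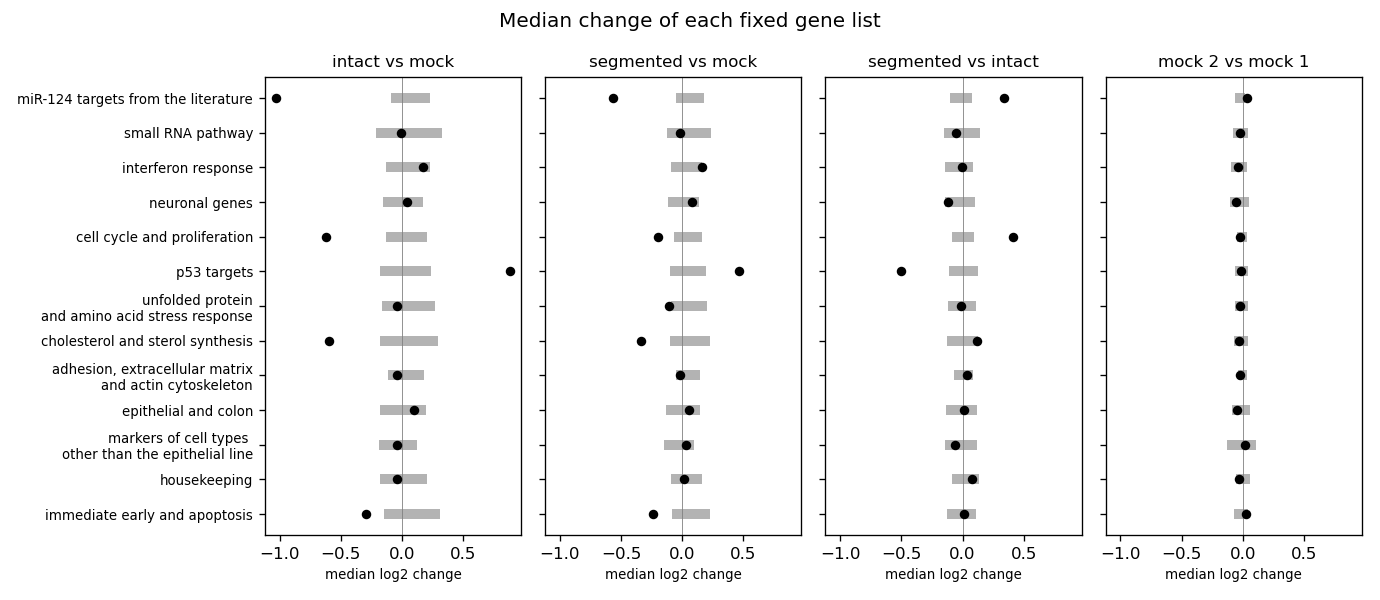
Points give the median log2 change of each of the 13 gene lists in 4 comparisons, including mock 2 against mock 1, and grey bars span the middle 95% of 10000 random lists of the same size and like level. The literature targets stand at -1.03 with the intact duplex and at -0.57 with the segmented one, and the p53 targets at 0.88 and 0.46.

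The direct difference between the duplexes passed limma's test for 0 of 19798 genes, with a smallest adjusted p of 0.181; 3273 genes had an unadjusted p under 0.05. With the trended and robust prior 2412 genes passed, 1061 lower and 1351 higher with the segmented duplex, and 1850 passed when the dimmest 40% of genes were left out. The values, from 1 array on each side, were higher with the segmented duplex for ARSB, a lysosomal sulfatase gene (by 2.54), the spermidine synthase gene SRM (2.26), CCNE2 (2.21), the histone chaperone gene ASF1B (2.19) and ICAM3 (2.12). All 5 had fallen with the intact duplex. Against mock, the segmented change of ARSB was -0.13, and 2 of its 4 probe sets went the other way. Whether its probe sets agree on the difference between the duplexes was not examined. Values were lower with the segmented duplex for PLA2G4D (-2.81), C2orf66 (-2.15), ACTA2 (-2.06), H2BC11 (-1.96) and MUC19 (-1.89), which had risen with the intact duplex.

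The literature targets of miR-124 spanned a wide range of differences between the duplexes. For CTDSPL the segmented minus intact difference was -0.09 (limma 95% interval -0.48 to 0.30), for CD164 0.32 (-0.17 to 0.80), for VAMP3 0.35 (-0.05 to 0.74), for CDK6 0.35 (-0.04 to 0.74) and for IQGAP1 0.36 (-0.04 to 0.77). Between these and the largest differences stood CTDSP1 at 0.47 (0.03 to 0.91), LAMC1 at 0.50 (0.11 to 0.89), RHOG at 0.59 (0.19 to 0.99), AHR at 0.60 (0.18 to 1.02) and SUCLG2 at 0.86 (0.46 to 1.26). For PTBP1 it was 1.35 (0.96 to 1.74), for ITGB1 1.55 (1.15 to 1.96) and for PLOD3 1.58 (0.93 to 2.23). COL12A1, a gene outside the lists, had a difference of 0.00 (-0.39 to 0.39). These intervals are for single genes and are not adjusted for the number of genes. Their width comes from the mock pair and limma's prior, and holds no spread between transfections with a duplex. The median difference of the 55 literature targets was 0.34, above all 10000 random lists, and adjusted over the list alone 13 members were higher and 1 was lower with the segmented duplex.

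The median difference was 0.41 for the cell cycle list, also above all random lists, and -0.50 for the p53 targets, below all of them. Adjusted over the list alone, 16 cell cycle genes were higher and 0 lower with the segmented duplex, and 9 p53 targets were lower and 0 higher. CCNE2 (2.21), CDK2 (1.84), RRM2 (1.80) and CDC25A (1.62) led the cell cycle list, and TP53I3 (-1.22), XPC (-0.87) and FAS (-0.86) the p53 targets. For sterol synthesis the median was 0.12 at percentile 96.5, with 2 members higher adjusted over the list alone. Medians of the remaining lists lay inside the middle 95% of random lists: immediate early and apoptosis 0.01, interferon response -0.00, neuronal -0.12, small RNA pathway -0.05, unfolded protein and amino acid stress -0.01, adhesion 0.03, epithelial and colon 0.01, other cell types -0.06 and housekeeping 0.08.

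**Figure D3:**
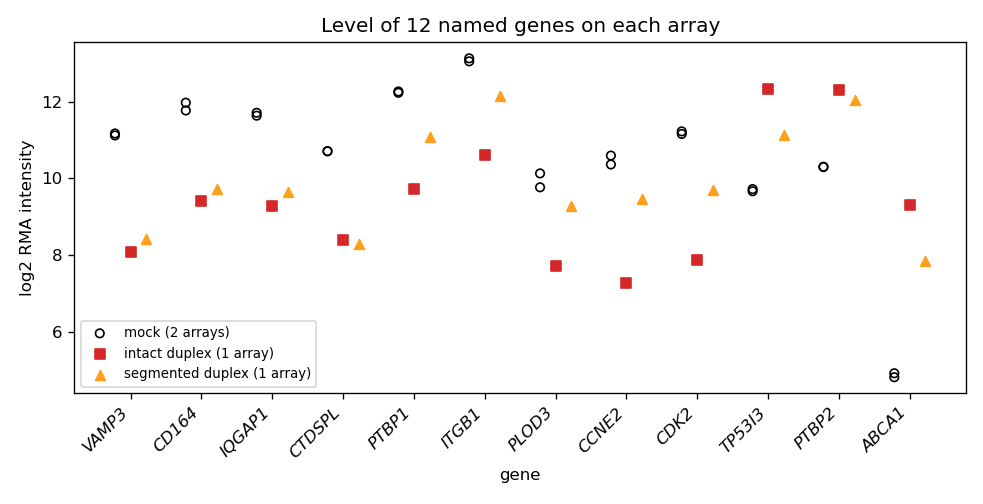
Log2 RMA intensity of 12 genes on each array, with open circles for the 2 mock arrays, squares for the intact duplex and triangles for the segmented duplex. For VAMP3, CD164, IQGAP1 and CTDSPL both duplexes stand close together and below mock, while for PTBP1, ITGB1, PLOD3, CCNE2 and CDK2 the segmented duplex stands between mock and the intact duplex. Literature targets with intermediate differences are not drawn.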

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

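All tests of explanations in this part were chosen after the results were seen. The gene lists below stood out because the difference between the duplexes passed limma's test adjusted over the list alone for some members. Single genes stood out because they lay on opposite sides of both mock arrays with the 2 duplexes. Only the genes named by rule, without the list examples, were checked for this. Probe sets outside the gene-level comparisons stood out because they held a signal above that between the mock arrays.

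The cell cycle list stood out because 16 members differed between the duplexes adjusted over the list alone, all of them higher with the segmented duplex, and its median was -0.62 with the intact and -0.20 with the segmented duplex. If the segmented duplex gave the whole response at 1 lower scale, the list would sit where other genes with the same intact change sit. It lay at percentile 99.72 among 10000 random lists matched on the intact change, the middle 95% of whose medians ran from -0.48 to -0.24. The genes of a random list are drawn singly, so genes that move together on 1 lone array could stray further than these lists. Of the parts of the cell cycle list, the 19 mitosis members lay furthest out, with a segmented median of -0.01 at percentile 99.78. This argues against 1 scale for them as far as such lists can show, and the parts were not tested against each other. The difference between the duplexes was not confined to mitosis: in wider lists its median was 0.83 over 38 replication genes and 0.38 over 31 mitosis genes. In the cell cycle list it was largest for CCNE2, CDK2, RRM2 and CDC25A. The 18 S phase and replication members, at percentile 71.9, and the 10 other members, at percentile 68.0, lay inside the middle 95% of matched lists. Those ranges were wide, from -0.91 to -0.39 and from -0.83 to -0.22. For these members 1 scale was thus neither argued against nor shown. Compression of bright signals on 1 array was argued against for the list's difference, which lay at percentile 100 among lists of like level. This is the placing already given for that difference, and it does not bear on the departure of the mitosis members from 1 scale. What stays open for the mitosis members is a biological difference between the duplexes, as a hypothesis, along with anything particular to 1 of the lone arrays, such as cell density at harvest, which the design does not separate from the duplex.

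Literature targets of miR-124 stood out with 14 members that differed between the duplexes adjusted over the list alone. Over all 55 measured targets the difference between duplexes ran from -0.78 to 1.58, with an SD over genes of 0.486 against 0.153 for the difference of the mock arrays, a ratio of 3.17 (95% bootstrap interval 2.16 to 4.90). Less the across-gene slope of 0.587 the ratio was 2.48 (1.71 to 3.86). Neither value decides between array noise, 1 scale factor with noise and a difference from target to target, because no duplex has a second array and the spread between separate transfections is unmeasured. As a group the targets lay inside the middle 95% of lists matched on the intact change, with a segmented median at percentile 26.5. The p53 targets did too, at percentile 20.3. Neither placing shows that 1 scale holds.

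Other lists with members whose difference between duplexes passed adjusted over the list alone were the p53 targets with 9, all lower with the segmented duplex, the adhesion list with 3, neuronal genes with 2 (RTN1, at -1.58, had the largest difference), sterol synthesis with 2 and markers of other cell types with 1, ACTA2. C2orf66 rose with the intact duplex (1.99) and stood at -0.17 with the segmented duplex, which did not pass (limma adjusted p = 0.606): its segmented level of 4.72 was close to the 4.74 of mock array 2, so no fall was shown. The difference between duplexes was -2.15, with a limma adjusted p of 0.181. AHR stood at -0.23 and 0.37, neither past the test (limma adjusted p = 0.278 and 0.180), a difference of 0.60 with a limma adjusted p of 0.231. Genes named only as list examples were not checked for opposite sides, and some of them, such as TLN1 (-1.33 intact and 0.10 segmented), also lay so. Of 16819 probe sets without a listed gene, 919 stood at least 2-fold from both mock arrays with the intact duplex and 322 with the segmented duplex, against 83 that far apart between the mock arrays.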

How the results depend on the processing

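Values from a different mock array for each duplex, at r = 0.770 and 0.766, were listed as alternatives after the data were seen; the other alternatives were planned. Directions of the literature target, cell cycle, p53, sterol and immediate early medians held under every alternative run. The trended and robust prior gave 7809 genes for the intact duplex, 5415 for the segmented duplex and 2412 for their difference; of the 4937 and 1186 genes called without it, 4848 and 1186 were among these. With the dimmest 40% left out, 4781 genes passed for the segmented duplex and 1850 for the difference, r was 0.897 and the target median with the segmented duplex was -0.63; the cause was not tested. At 2-fold, 2046 and 757 genes stood apart from both mock arrays, fewer by construction. Leaving out each mock array gave r from 0.852 to 0.860 and a target median of -0.63 to -0.57 with the segmented duplex. It gave 5435 to 5765 and 3155 to 3479 genes at 1.5-fold, which cannot be fewer by construction, since 1 difference is asked for in place of both. Median centring, which shifts all genes of an array by the same constant, moved the target medians to -1.12 and -0.63. The mean of all probe sets gave -0.91 with the intact duplex and 0.30 for the difference, and the cause of that was not tested. Of the values of named genes under alternatives, 488 counted as unchanged, 38 came to pass and 2 no longer passed. The 488 include values without 1 mock array, which have no test and by the rule used could not count as moved. Of list medians, 142 moved by less than the spread and 130 by more. For comparisons with mock this spread is the SD of the 2 values without 1 mock array, which are themselves among the values judged. Limma without 1 mock array has no residual degree of freedom, so no such counts exist, nor could the duplexes be fitted alone. No paired analysis was possible because only the mock group has more than 1 numbered array. Seed site and 7-base word results and their alternatives were not run. Genes near the dim end have the least certain folds.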

Other observations

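All tests and the 5 gene lists in this part were chosen after the data were examined. Genes of DNA replication and of mitosis, both parts of the cell cycle, were looked at separately. Of 38 measured S phase and replication genes, 18 of them on the cell cycle list, 33 fell and 0 rose with the intact duplex, with a median of -1.48 below all 10000 random lists. DTL fell by 3.69, MCM10 by 3.58, ASF1B by 2.82 and SLBP, which binds histone messenger RNA, by 2.43. With each duplex, 36 of the 38 lay below mock, whether past the test or not. With the segmented duplex 11 fell, the median was -0.60, and DTL stood at -1.75 and MCM10 at -1.96. Of 31 mitosis genes, 19 of them on the cell cycle list, 7 fell and 1 rose with the intact duplex, with a median of -0.38 at percentile 0.02; BUB1B fell by 1.35 and NEK2 rose by 0.60. With the segmented duplex 0 of them passed and the median was 0.02, at percentile 36.1. Among random lists matched on the intact change, the segmented median lay at percentile 92.0 for replication and 99.99 for mitosis.

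Some core histone genes rose while others fell. Of 50 measured, most of them dim, 12 rose and 2 fell with the intact duplex, and 8 rose and 0 fell with the segmented duplex; the list medians were 0.08 and 0.02. With the dimmest 40% of genes left out, and so over the brighter histone genes only, they were 1.40 and 0.71. With arrays centred on their medians they were -0.01 and -0.04. H2BC21 rose from 8.58 ± 0.10 (SD, n = 2) to 12.27 and 10.78, H3C10 by 3.18 and 1.92, and H2AC6 by 2.59 and 1.84, while H2AC20 fell by 2.03 and H4C3 by 2.00 with the intact duplex. Near-identical histone genes can share probe signal. ABCA1 (4.46 and 2.98) and ABCG1 (2.72 and 2.29), cholesterol exporters induced by liver X receptors, rose with both duplexes, although 1 of 4 ABCG1 probe sets went the other way. The 14 measured liver X receptor targets together had medians of 0.07 and -0.07; the intact one was -0.17 with the dimmest 40% of genes left out and -0.02 with arrays centred on their medians, so its direction is not settled. LPCAT3 fell by 1.34 and 1.00. Of 17 vacuolar proton pump genes, 5 rose and 2 fell with the intact duplex, with a median of 0.43 at percentile 99.64: ATP6V0E1 and ATP6V0A2 fell by 3.55 and 1.45, and ATP6V1G2, a neuronal subunit, rose by 3.26. With the segmented duplex 1 rose and 2 fell, with a median of 0.20 at percentile 94.2.

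The changes with both duplexes ran in parallel across genes. Noise private to each of the shared mock arrays was argued against as the whole source. With a different mock array for each duplex the lower covariance was still 0.249, against at most 0.00911 in simulated unchanged arrays. A deviation common to both mock arrays would remain after this split and enter both sets of changes, so it was not tested. A response to any transfected RNA duplex cannot be told apart from an effect of the miR-124 sequence for most genes, because no array of an unrelated duplex was analysed here. The interferon response list, which such a response might move, lay at percentile 97.36 with the segmented and 92.21 with the intact duplex. Whether the seed drove the fall of the literature targets was not tested: the labels give the segmentation only as a code, and no seed sites were searched.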
